A study of Drosophila melanogaster with 18 samples.

How the data were processed

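The series holds 18 samples of total RNA from hand-dissected egg chambers of stages 9 to 10, taken from females aged 6 to 8 days that had been kept with yeast at 23 °C for 24 h. Per the labels' protocols, 3 µg of RNA per sample was converted to biotinylated cRNA and hybridized to the array, and extraction, labelling and hybridization were done in parallel within each of 2 rounds. Groups were taken from the sample titles, with 3 samples in each of 6 groups.

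The authors' deposited value table holds log2 values of 14010 probe sets, 1 column per array, and no column was left unmapped. The submitters' processing notes name the affy package, with no version, and the background correction and summary method were not given in the sources used here. The base of the logarithm was settled from the data, since the highest value of 13.3 is 9860 as a power of 2 and would be 578050 as a natural log, beyond the range of the scanner. Array medians within a round lie close together and differ between rounds, so the table appears to have been normalized within each round by the authors, and no further normalization was applied. The table was used without detection calls, so folds of genes whose lower group lies near the bottom of the scale depend on the authors' background handling. No 2 arrays held identical values, and arrays of a group had a mean Spearman correlation of 0.959 to 0.969 with each other.

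Probe sets were named from the platform annotation, updated through a table of the Release 6 plus ISO1 MT assembly that was used for names and neighbouring genes only. Of the probe sets other than 44 Affymetrix controls, 12442 had 1 gene, 327 several and 1197 none, and only the first were named. Of those 12442, 12393 were matched by gene number and 42 by symbol, 7 kept the older name, and 38 changed name. They covered 10825 genes, 1216 of them with several probe sets. A gene with several was represented by the one with the highest mean over the 18 arrays, and no gene had called probe sets of opposite sign in a comparison.

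The 13966 remaining probe sets were fitted with limma 3.58.1 in R 4.3.3 as 6 group means over all 18 arrays, with 12 residual degrees of freedom and moderated variances (prior degrees of freedom 1.31), which assumes that the groups share 1 spread. The comparisons were each perturbation against the wild type of its round, EGFR gain against EGFR loss and against BMP gain, the BMP gain response minus the BMP loss response, and wild type A against wild type B. Contrasts were called at a Benjamini-Hochberg adjusted p under 0.05. For gene groups, 24 lists of signalling pathways, eggshell and yolk genes, processes and markers of other cell types were tested with camera at an inter-gene correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry. A list is given as called or not called by camera at the correlation of 0.01, unless another test is named. In the comparisons with wild type and both direct comparisons of perturbations every called probe set had arrays that did not overlap between the groups, which 10% of probe sets show by chance. Overlaps of comparisons with shared controls were set beside 50 simulations of unchanged groups.

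Genes named in the text follow a rule. It took the driven genes and a fixed set of patterning genes in every comparison. It took the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap and whose higher group reached the table's median of 4.33, and up to 4 called members of each list. The choice among several probe sets of a gene in that ranking was left open by the rule and settled as the representative probe set after values had been seen. The rule was not applied between the wild types, where the rounds differ by an overall shift. The eye colour marker white, and rho, pnt, vn, brk and Fas3 of the patterning set, were not named on the array here. The groups, comparisons, lists, naming rule and most alternatives were fixed before the data were examined.

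The fit was tested on simulated data made from the wild type means of each round, with 13966 probe sets and independent normal noise. That noise had the same pooled SD in every group, as the fit assumes. False calls that come from a wider spread in a single group could therefore not show. Changes were planted only in probe sets at or above the median of all means, so recovery among dimmer probe sets was not tested. In the EGFR gain comparison 55.2%, 89.6% and 92.4% of planted changes of 1.5-, 2- and 4-fold were recovered with 9 false calls among 167. The shares were 52.2%, 80.6% and 92.4% in EGFR loss with 12 false among 162 calls, 52.2%, 88.1% and 95.5% in BMP gain with 5 among 162, and 56.7%, 85.1% and 97.0% in BMP loss with 6 among 165. Alternatives were fits to the arrays of a comparison or of a round alone, an intensity trend with robust moderation, array weights, a filter on dim probe sets, quantile normalization, median centring, the round as a block with all wild types, the replicate number as a block, each array left out and a 2-fold minimum. Added after the data were seen were the actin 3' minus 5' difference as a covariate and both replicate 3 arrays of the EGFR groups left out.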

Results

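RNA was measured in Drosophila egg chambers of stages 9 to 10, when the follicle cells around the oocyte are being patterned and begin to make the eggshell. Each of 18 samples was hybridized to 1 first-generation Affymetrix Drosophila genome array. In 4 genotypes the CY2-GAL4 line, which drives transgenes in follicle cells, was crossed to a UAS transgene that raised or lowered a single signalling pathway. Constitutively active lambda-Top gave gain of function of the epidermal growth factor receptor (EGFR), and a dominant-negative receptor gave EGFR loss of function. Activated Thickveins (tkv), a type I receptor of the bone morphogenetic protein (BMP) pathway, gave BMP gain of function, and the inhibitory Smad encoded by Dad gave BMP loss of function. OreR flies were the wild type, and every group held 3 arrays. The arrays were run in 2 rounds. Round 1 held wild type A, EGFR gain, EGFR loss and BMP gain, and round 2 held wild type B and BMP loss, so each perturbation was set against the wild type of its own round. Flies with the driver alone were not analysed here, so a difference from wild type can come from the strain or the driver as well as from the pathway. Each replicate held 100 egg chambers gathered in groups of 20 from the 300 of its genotype, so the p-values measure only the spread between these samples, which may be technical. The median log2 value per array was 4.44 to 4.51 in round 1 and 4.02 to 4.04 in round 2, and precision was limited by the number of arrays. In what follows means carry their SD over 3 arrays, and changes are on the log2 scale with their SE and the adjusted p from limma.

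The driven genes were read first, since they check the labels. Egfr, by the probe set that rose, stood at 6.29 ± 0.20 in EGFR gain against 4.42 ± 0.08 in wild type A, a rise of 1.87 ± 0.16 (adjusted p = 2.7e-05). Its other probe set, the brighter in wild type, gave -0.12 ± 0.21 (0.88). In EGFR loss neither Egfr probe set was called, at -0.32 (0.35) and 0.03 (0.97), so the arrays gave no reading of the dominant-negative transgene. The BMP receptor gene tkv, by its dimmer probe set, rose from 6.53 ± 0.07 to 8.34 ± 0.09 in BMP gain, by 1.81 ± 0.18 (6.6e-05), while the brighter gave 0.16 ± 0.10 (0.62). Dad rose from 3.21 ± 0.28 in wild type B to 7.60 ± 0.09 in BMP loss, by 4.39 ± 0.66 (0.0031), or 21.0-fold. Which part of a transcript each probe set reads was not given in the sources used here.

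**Figure D1:**
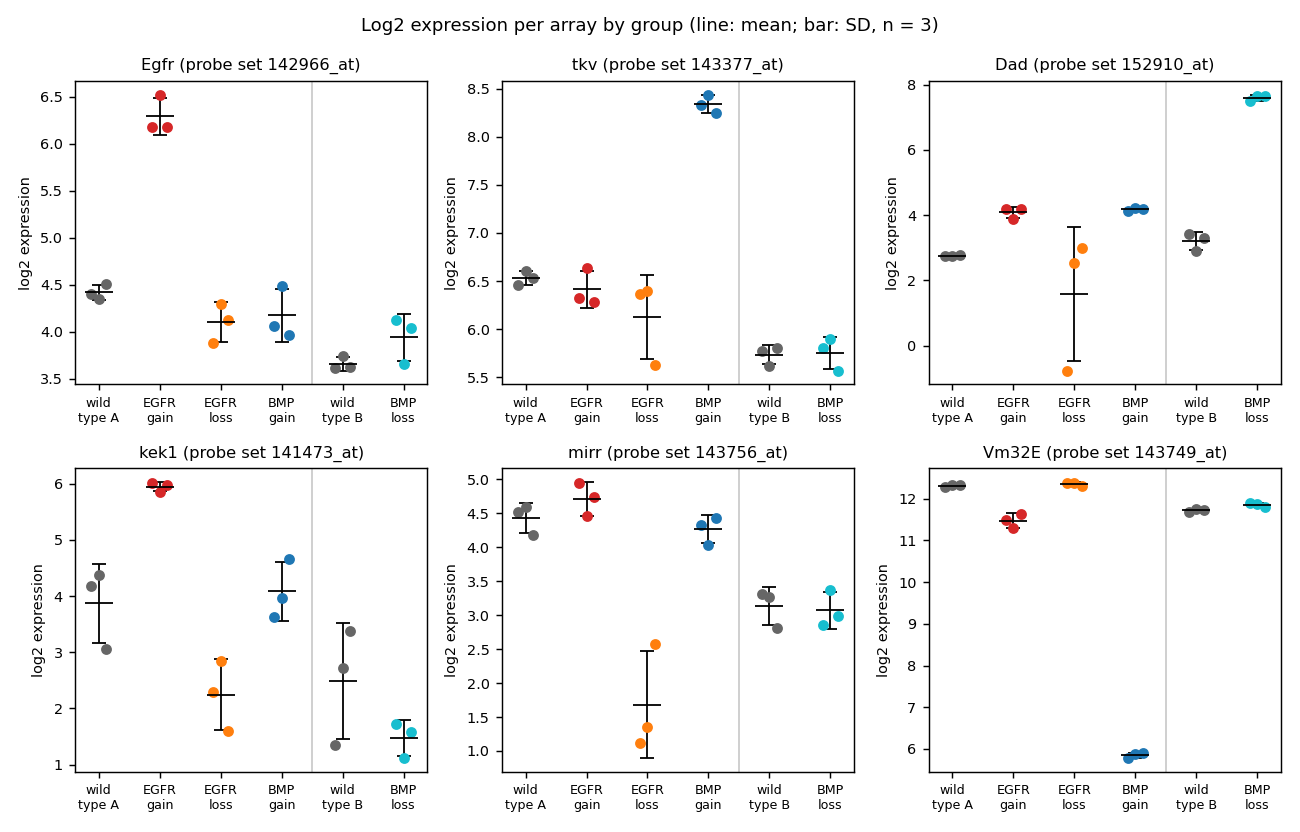
Log2 array values of Egfr, tkv, Dad, kek1, mirr and Vm32E in the 6 groups, with a point per array, a line at the mean and a bar for the SD (3 arrays each), and a grey line between the hybridization rounds. Egfr and tkv are drawn by the probe set that rose, levels compare only within a round, and within round 1 Egfr is highest in EGFR gain, mirr is lowest in EGFR loss and Vm32E is 5.85 in BMP gain against 12.31 in wild type A.

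EGFR gain of function was compared with wild type A to ask which transcripts follow the receptor when it is constitutively active. Egg chambers with active EGFR had more RNA of kek1, which encodes a feedback inhibitor of EGFR, of the Toll-family receptor gene 18w and of genes for antimicrobial peptides. They had less RNA of several eggshell genes. kek1 rose by 2.08 ± 0.49 (adjusted p = 0.037), from 3.87 ± 0.71 to 5.94 ± 0.08, and 18w by 1.15 ± 0.16 (0.0013). Of 7 measured EGFR response genes 1 rose and 6 were not called, with the same count adjusted over the list alone, and the list as a whole was not called by limma's camera test (0.20). The fry test, of another hypothesis, called the list higher (adjusted p = 0.021). The feedback inhibitor genes aos, at 2.32 ± 1.16 (0.42), and sty, at 0.76 ± 0.55 (0.62), and the dorsal patterning gene mirr, at 0.28 ± 0.31 (0.79), were not called. The antimicrobial peptide genes Mtk and Drs rose by 3.67 ± 0.90 (0.045) and 2.47 ± 0.57 (0.034). Of 9 measured immune response genes 2 rose, none fell and 7 were not called (4 rose adjusted over the list alone), and the list was higher (0.0034; adjusted p = 0.046 with an estimated correlation).

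Of 11 measured genes for the vitelline membrane and early eggshell, 3 fell in EGFR gain and 8 were not called (4 fell adjusted over the list alone). Vm32E changed by -0.84 ± 0.08 (adjusted p = 7.6e-05), psd by -0.51 ± 0.10 (0.012) and Vm26Ac by -0.37 ± 0.09 (0.043). The list was lower in the camera test (0.014), but not called at adjusted p = 0.28 with an estimated correlation. Among 7 chorion genes, which encode the outer eggshell, Cp15 fell by 1.53 ± 0.36 (0.036) and 6 were not called, and the list was lower (0.0042; adjusted p = 0.44 with an estimated correlation). Of 16 cell cycle genes Mcm3 (-0.42) and dup (-0.36), both for DNA replication, fell and 14 were not called (5 fell adjusted over the list alone), with the list lower (0.012; adjusted p = 0.44 with an estimated correlation). The largest changes lay elsewhere. The cytochrome P450 genes Cyp28d1 and Cyp6a17 rose by 5.56 ± 0.33 (8.7e-07) and 4.66 ± 0.28 (9.5e-07), and CG31326 by 3.86 ± 0.23 (8.7e-07). The ionotropic receptor gene Ir76a fell by 3.96 ± 0.44 (0.00023), PICK1 by 3.82 ± 0.38 (8.1e-05) and the zinc finger gene dati by 1.60 ± 0.21 (0.00082). Of 20 detoxification genes 4 rose and 3 fell (4 and 5 adjusted over the list alone), and the list as a whole was not called (0.96), with a median of -0.23 and a mean of 0.23.

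Of 13966 probe sets tested, limma called 392 in EGFR gain, 212 higher and 180 lower, 99 of them by at least 2-fold, and 1912 had an unadjusted p under 0.05. The number of calls was 62 in a fit to these 6 arrays alone, and 220 without EGFR gain replicate 1, 257 without EGFR gain replicate 2, 219 without wild type A replicate 2 and 226 without wild type A replicate 3. Any of the 6 arrays left out ended the calls of kek1 and Mtk (highest adjusted p 0.17 and 0.15) and of Mcm3 (0.14), and some of them those of Drs (0.15), Cp15 (0.16), Vm26Ac (0.17), dup (0.17) and psd (0.051), while 17 of 33 named calls held with every single array left out. In the fit to these 6 arrays alone 12 of the 33 held, 18w and Cyp28d1 among them, and those of kek1 (0.13), Vm32E (0.079), GstD9 (0.070), Ir76a (0.11), dati (0.13) and others ended.

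EGFR loss of function was compared with wild type A to ask which transcripts need the receptor. Lower were mirr, an Iroquois homeobox gene of the dorsal anterior follicle cells, the BMP receptor gene tkv and all 3 yolk protein genes. mirr went from 4.43 ± 0.22 to 1.68 ± 0.79, a change of -2.74 ± 0.31 (adjusted p = 0.00025) whose size is uncertain, since the lower value lies under the 25th percentile of those arrays (1.90 to 2.03), and 18w fell by 0.80 ± 0.16 (0.013). kek1, at -1.62 ± 0.49, missed the threshold (0.099). Of 7 EGFR response genes 1 fell and 6 were not called (3 fell adjusted over the list alone), and the list was not called (0.068). The fry test called that list lower (adjusted p = 0.00044). By its brighter probe set tkv fell by 0.98 ± 0.10 (9.6e-05), with the dimmer at -0.40 (0.27). In the BMP pathway list cv-2, an extracellular BMP regulator, rose by 0.94 ± 0.22 (0.038). That list was not called (0.19), while fry called it lower (adjusted p = 0.0023).

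The yolk protein genes are expressed in follicle cells and fat body, and all 3 fell in EGFR loss, each also adjusted over the list alone. Yp3 changed by -0.62 ± 0.06 (adjusted p = 6.6e-05), Yp1 by -0.52 ± 0.06 (0.00025) and Yp2 by -0.44 ± 0.07 (0.0023), and the list was lower (1.1e-07; adjusted p = 0.0089 with an estimated correlation). These genes lie near the top of the scale, with Yp1 at 12.72 ± 0.03 in wild type A. Of 7 chorion genes Cp38 and Cp7Fc fell (-1.61 ± 0.38 at 0.035, and -1.54 ± 0.39 at 0.049), none rose and 5 were not called (3 fell adjusted over the list alone). The list was not called (0.59), and its median of 0.25 and mean of -0.31 differed in sign. Of 23 germline genes pgc rose, piwi and osk fell and 20 were not called (1 rose and 4 fell adjusted over the list alone), and the list was not called (0.079). Among the most changed genes zld, a zinc finger transcription factor, fell by 2.70 ± 0.47 (0.0070), while dpy, an extracellular matrix gene, and PGRP-SC2, a peptidoglycan amidase gene, rose by 2.21 ± 0.35 (0.0032) and 2.24 ± 0.22 (8.1e-05). Cyp28d1 rose by 5.90 ± 0.33 (7.5e-07) and CG7742 by 3.89 ± 0.24 (1.8e-06).

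Some genes of tissues outside the follicle were higher in EGFR loss. Of 16 muscle genes Prm and Mlc2 rose by 1.31 ± 0.24 (adjusted p = 0.010) and 0.95 ± 0.21 (0.028), and 14 were not called (3 rose adjusted over the list alone). Of 7 fat body genes Obp99b and Lsp2 rose by 2.80 ± 0.65 (0.035) and 0.93 ± 0.23 (0.049), and 5 were not called (3 rose adjusted over the list alone). Neither list was called (0.079 for muscle and 0.062 for fat body), while the fry test called both higher (adjusted p = 0.039 and 0.021). RNA quality differed in a single array of this group. The actin control probe sets had a 3' minus 5' difference of 2.89 in EGFR loss replicate 3. It was 1.12 in EGFR loss replicates 1 and 2 and at most 1.20 in wild type A. In EGFR gain replicates 1 and 3 it was 1.37 and 1.63, and the GAPDH difference of 2.19 and 2.45 there and 2.68 in EGFR loss replicate 3 also exceeded the highest wild type A array (2.07). Affymetrix control probe sets were called in this comparison alone among those with wild type, 5 of 44. They were the 5' and middle GAPDH probe sets, both lower, and BioB-M, BioC-5 and MurIL10, all higher. The last named are not controls for fly RNA and do not bear on its quality. Without EGFR loss replicate 3 Prm stood at 1.20 (0.041), Mlc2 at 0.91 (0.075), Obp99b at 2.36 (0.11) and Lsp2 at 0.89 (0.12). There mirr stood at -3.19 (1.6e-05) and Yp3 at -0.63 (0.00026). The EGFR response and cell cycle lists, both lower, then passed the threshold (0.039 and 0.027), but neither was called with an estimated correlation (adjusted p = 0.17 and 0.38).

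In EGFR loss limma called 443 of 13966 probe sets, 236 higher and 207 lower, 120 by at least 2-fold, with 2329 at an unadjusted p under 0.05. The number was 28 in a fit to these 6 arrays alone, 255, 246 and 233 without wild type A replicates 1, 2 and 3, 295 without EGFR loss replicate 2 and 346 without EGFR loss replicate 3. Some arrays left out ended the calls of 18w (highest adjusted p 0.056, without wild type A replicate 1), Cp38 (0.13), Cp7Fc (0.16), Obp99b (0.14), Lsp2 (0.17), Mlc2 (0.11), cv-2 (0.13) and osk (0.098), while 24 of 39 named calls held with every single array left out. In the fit to these 6 arrays alone 8 of the 39 held, Cyp28d1, PGRP-SC2 and dpy among them, and those of mirr (0.13), tkv (0.065), Yp3 (0.12), Yp1 (0.17), Yp2 (0.23), 18w (0.26), zld (0.098), Prm (0.24) and others ended.

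BMP gain of function was compared with wild type A to ask which transcripts follow the activated BMP receptor. The vitelline membrane gene Vm32E was 87.7-fold lower, from 12.31 ± 0.03 to 5.85 ± 0.06, the change with the lowest p of the comparison. Another gene of that family, Vm26Ac, was 3.505-fold lower, and several chorion genes were lower too. The germline differentiation gene bam was 4.15-fold higher, and magu, which encodes a secreted BMP modulator, 2.01-fold higher. Vm32E changed by -6.45 ± 0.08 (adjusted p = 5.3e-15) and Vm26Ac by -1.81 ± 0.09 (1.2e-07). Of 11 vitelline membrane and early eggshell genes these 2 fell, none rose and 9 were not called (8 fell adjusted over the list alone), and the list was lower (2.5e-12; adjusted p = 0.00090 with an estimated correlation). Vm26Aa and Vm34Ca, at -0.09 and -0.12, were not called. Of 7 chorion genes Cp38 fell by 2.50 ± 0.38 (0.0022), Cp7Fc by 1.68 ± 0.39 (0.037) and Cp36 by 1.31 ± 0.32 (0.047), and 4 were not called (5 fell adjusted over the list alone). The chorion list was lower (8.0e-06), but not called at adjusted p = 0.23 with an estimated correlation.

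In BMP gain bam rose by 2.05 ± 0.13 (adjusted p = 1.7e-06). Of 18 BMP pathway components magu rose by 1.01 ± 0.17 (0.0053) and 17 were not called, also adjusted over the list alone, and the list was not called (0.15). The fry test called that list higher (adjusted p = 0.0018). Dad, a transcriptional target of BMP signalling, was not called, at 4.19 ± 0.05 against 2.76 ± 0.02 in wild type A, a difference of 1.43 ± 0.66 (0.44). Its SE is pooled over groups and holds the SD of 2.06 in EGFR loss, and in fits to the 6 arrays of a comparison alone Dad passed the threshold in BMP gain (adjusted p = 0.0079) and, at 1.33, in EGFR gain (0.033). 18w rose by 1.14 ± 0.16 (0.0012). Yp3 rose by 0.65 ± 0.06 (3.2e-05), while Yp1 and Yp2 were called only adjusted over the list alone, and the yolk list was higher (0.00019; adjusted p = 0.049 with an estimated correlation). Of 16 cell cycle genes the replication genes PCNA and Mcm6 rose by 0.54 ± 0.08 (0.0030) and 0.53 ± 0.10 (0.012) and 14 were not called (3 rose adjusted over the list alone), and the list was higher (0.0065; adjusted p = 0.46 with an estimated correlation). The EGFR ligand gene spi fell by 0.60 ± 0.14 (0.034). Mur2B fell by 4.37 ± 0.64 (0.0019), alpha-Est10 by 2.94 ± 0.33 (0.00026) and CG17270 by 3.37 ± 0.15 (3.6e-08). The muscle and fat body lists were not called (0.93 and 0.76).

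In BMP gain limma called 334 of 13966 probe sets, 163 higher and 171 lower, 104 by at least 2-fold, with 1579 at an unadjusted p under 0.05. The number was 95 in a fit to these 6 arrays alone, and 221 and 210 without wild type A replicates 2 and 3. Any of the 6 arrays left out ended the call of spi (highest adjusted p 0.12), and some of them those of Cp7Fc (0.15, without BMP gain replicate 1), Cp36 (0.18, without BMP gain replicate 1) and Mcm6 (0.054), while 23 of 35 named calls held with every single array left out. In the fit to these 6 arrays alone 15 of the 35 held, those of Vm32E, Vm26Ac, bam and Yp3 among them, and those of 18w (0.060), magu (0.084), spi (0.072), Cp38 (0.089), PCNA (0.084) and others ended.

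BMP loss of function was compared with wild type B, the control of round 2. Apart from the rise of the driven gene Dad, the EGFR ligand gene spi was 1.76-fold lower and the eggshell genes yellow-g and yellow-g2 3.15-fold and 4.30-fold lower. The signal gene hh, of the Hedgehog pathway, was lower between dim values. The transcription factor gene bun, which both pathways regulate in follicle cells, was 1.67-fold lower, and lower in the other perturbations too. spi fell by 0.82 ± 0.14 (adjusted p = 0.0058), from 6.23 ± 0.09 to 5.41 ± 0.19, and bun by 0.74 ± 0.12 (0.0066). spi was also called lower in BMP gain, as given above, so it went the same way in both BMP perturbations. Against wild type A bun fell by 0.59 ± 0.12 in EGFR gain (0.022) and by 0.54 ± 0.12 in EGFR loss (0.034). These calls held with only 1 of the 6 arrays left out (highest adjusted p 0.096 and 0.11). In BMP gain bun stood at -0.49 ± 0.12 (0.060). It was not called between EGFR gain and EGFR loss, at -0.05 ± 0.12 (0.92). Nor was it between the BMP responses, at 0.24 ± 0.18 (0.79), so its fall may come from the strain or the driver. hh fell by 3.14 ± 0.51 (0.0055), from 1.93 ± 0.29 to -1.21 ± 0.40, a size that is uncertain since the lower value lies under the 25th percentile of those arrays (1.54 to 1.58). The other 5 of 6 Hedgehog and Wnt genes were not called (1 fell adjusted over the list alone), nor was the list (0.52). Of 18 BMP pathway components Dad rose, the type II receptor gene put fell by 0.65 ± 0.14 (0.025) and 16 were not called (2 rose and 1 fell adjusted over the list alone), and the list was not called (0.52). The fry test called that list, which holds the driven gene Dad, higher (adjusted p = 0.012). Of 11 vitelline membrane and early eggshell genes yellow-g fell by 1.66 ± 0.37 (0.031) and yellow-g2 by 2.10 ± 0.43 (0.020), with 9 not called (1 rose and 2 fell adjusted over the list alone), and the list was not called (0.74). Vm32E, at 0.14, and Vm26Ac, at 0.27, were not called. Yp1 fell by 0.44 ± 0.06 (0.0013), and of 3 yolk genes the other 2 were not called (2 fell adjusted over the list alone), with the list lower (0.027) but not called at adjusted p = 0.28 with an estimated correlation. In the dorsoventral axis list spz, the gene for a Toll ligand, rose by 0.60 ± 0.09 (0.0029).

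Genes of detoxification went both ways in BMP loss, where of 20 measured genes 4 rose, 5 fell and 11 were not called (5 and 5 adjusted over the list alone), and the list as a whole was not called (0.82). Cyp6a17 rose by 4.84 ± 0.28 (adjusted p = 7.2e-07) and the glutathione S-transferase gene GstD1 by 2.30 ± 0.08 (4.7e-09), while GstE7 and GstE1 changed by -3.44 ± 0.25 (6.3e-06) and -2.35 ± 0.13 (3.6e-07). CG6426 rose by 4.33 ± 0.77 (0.0091) and CG12560 by 3.41 ± 0.17 (1.5e-07). Drep1, which encodes a DNase regulator, fell by 3.78 ± 0.38 (0.00011), and GLaz, for a lipocalin, by 2.46 ± 0.37 (0.0030). In all limma called 320 of 13966 probe sets, 156 higher and 164 lower, 83 by at least 2-fold, with 1869 at an unadjusted p under 0.05. The number was 55 in a fit to these 6 arrays alone, 183 without wild type B replicate 1, and 208, 212 and 200 without BMP loss replicates 1, 2 and 3. Some arrays left out ended the calls of yellow-g (highest adjusted p 0.12), yellow-g2 (0.079) and put (0.097), while 21 of 26 named calls held with every single array left out. In the fit to these 6 arrays alone 13 of the 26 held, those of Dad, hh and GstD1 among them, and those of spi (0.11), bun (0.15), yellow-g2 (0.089), Yp1 (0.12), Drep1 (0.11), GLaz (0.20) and others ended.

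**Figure D2:**
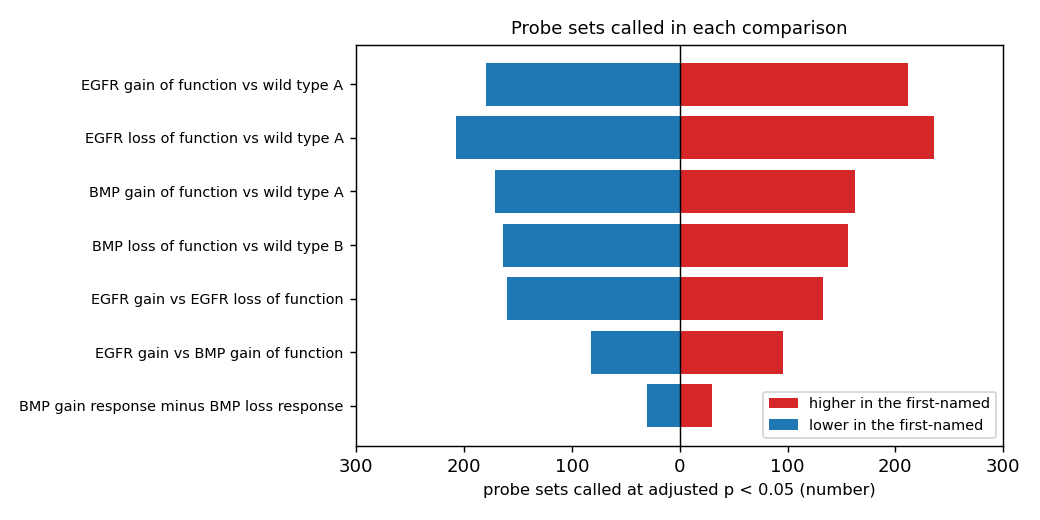
Number of probe sets called higher and lower by limma in each of 7 comparisons, as bars from 0, of 13966 tested. The counts fall from 443 in EGFR loss against wild type A to 60 for the difference between both BMP responses.

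EGFR gain was compared directly with EGFR loss, since both carry the driver and a transgene and were run in the same round. With the active receptor kek1 was 12.98-fold higher than with the dominant-negative one and mirr was higher too, both of the EGFR response list, and 18w, which is not of that list, was 3.85-fold higher. kek1 differed by 3.70 ± 0.49 (adjusted p = 0.0014), mirr by 3.03 ± 0.31 (0.00020) and 18w by 1.95 ± 0.16 (2.4e-05). Of 7 EGFR response genes 2 were higher and 5 not called (3 higher adjusted over the list alone), and the list was higher (0.00028; adjusted p = 0.011 with an estimated correlation). aos and sty, at 2.39 ± 1.16 (0.40) and 1.62 ± 0.55 (0.19), were not called. The receptor gene tkv was higher by 0.71 ± 0.10 (0.0015), and of 18 BMP pathway components tkv and shn were higher and 16 not called (4 higher and 2 lower adjusted over the list alone), with the list higher (0.043; adjusted p = 0.079 with an estimated correlation). puc, a target of JNK signalling, was higher by 0.87 ± 0.15 (0.0065). The 3 yolk protein genes were all higher, also adjusted over the list alone, Yp1 by 0.68 ± 0.06 (3.2e-05), and so was their list (1.9e-09; adjusted p = 0.0036 with an estimated correlation).

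Some muscle and fat body genes were lower in EGFR gain than in EGFR loss. Prm differed by -1.82 ± 0.24 (adjusted p = 0.0015), Mlc2 by -1.31 ± 0.21 (0.0050) and Mlc1 by -2.88 ± 0.64 (0.033), and 13 of 16 muscle genes were not called (4 lower adjusted over the list alone). The muscle list was lower (0.0013; adjusted p = 0.061 with an estimated correlation). Of 7 fat body genes Obp99b was lower and 6 not called (2 lower adjusted over the list alone), and the list was lower (0.043; adjusted p = 0.26 with an estimated correlation). Without EGFR loss replicate 3, the array with the actin difference of 2.89 beside 1.63 in EGFR gain replicate 3, the muscle list stood at 0.00083 (adjusted p = 0.10 with an estimated correlation) and the fat body list at 0.22, Mlc1 at -2.69 (0.10) and Obp99b at -2.50 (0.11). Of 9 immune response genes Mtk was higher by 4.13 ± 0.90 (0.031) and 8 were not called (1 higher adjusted over the list alone). The immune list was higher (0.020; adjusted p = 0.061 with an estimated correlation, and 0.12 without EGFR loss replicate 3). The BMP pathway list was not called without that array (0.073). Among eggshell genes Cp15 differed by -2.30 ± 0.36 (0.0038) and Vm32E by -0.88 ± 0.08 (9.7e-05), and the metalloproteinase inhibitor gene Timp by -1.30 ± 0.22 (0.0065). Of 11 vitelline membrane and early eggshell genes 1 was higher, 2 were lower and 8 not called (2 higher and 4 lower adjusted over the list alone). Of 7 chorion genes 2 were lower and 5 not called (3 lower adjusted over the list alone). Neither of these lists was called (0.31 and 0.20), while fry called the first lower (adjusted p = 0.011) and not the second (0.22).

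In this comparison limma called 293 of 13966 probe sets, 133 higher and 160 lower, with 112 of 313 higher once each array was centred on its median, and 88 by at least 2-fold, 49 higher and 39 lower, with 1882 at an unadjusted p under 0.05. The number was 2 in a fit to these 6 arrays alone, in which none of the 38 named calls held, and 174 and 173 without EGFR gain replicates 1 and 2. Any of the 6 arrays left out ended the call of Obp99b (highest adjusted p 0.12), and some of them those of Mtk (0.10), Mlc1 (0.14) and shn (0.056), while 22 named calls held with every single array left out.

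EGFR gain was also compared with BMP gain, as the activated forms of both receptors in the same round. Vm32E was 49.1-fold higher with active EGFR than with active BMP receptor, while bam and magu were 7.28-fold and 2.90-fold lower. Vm32E differed by 5.62 ± 0.08 (adjusted p = 3.3e-14), Vm26Ac by 1.43 (1.4e-06) and Mur2B by 3.95 ± 0.64 (0.0078), with its value in BMP gain under the 25th percentile of those arrays. Of 11 vitelline membrane and early eggshell genes 4 were higher and 7 not called (6 higher and 1 lower adjusted over the list alone), and the list was higher (1.0e-07; adjusted p = 0.0088 with an estimated correlation). bam differed by -2.86 ± 0.13 (7.2e-08), magu by -1.54 ± 0.17 (0.00038) and Yp3 by -0.79 (7.6e-06). Of 16 cell cycle genes 3 were lower, RnrL (-0.50), PCNA (-0.45) and Orc1 (-0.48), and 13 not called (11 lower adjusted over the list alone), with the list lower (2.8e-10; adjusted p = 0.022 with an estimated correlation). No gene of the immune response list was called among 9 (1 higher adjusted over the list alone), yet the list was higher (0.00068; adjusted p = 0.018 with an estimated correlation), with Mtk at 3.58 (0.087). 18w, which rose in both groups against wild type, differed by 0.01 (0.99), and kek1 by 1.86 ± 0.49 (0.11). The heat shock gene Hsp68 was higher by 2.67 ± 0.54 (0.028), a call that ended with some arrays left out (highest adjusted p 0.12). limma called 178 of 13966 probe sets, 96 higher and 82 lower, 66 by at least 2-fold, 46 higher and 20 lower, with 1572 at an unadjusted p under 0.05. The number was 41 in a fit to these 6 arrays alone, in which 7 of 17 named calls held, and 96 and 110 without EGFR gain replicates 1 and 2, and 89, 94 and 106 without BMP gain replicates 1, 2 and 3.

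The BMP groups were run in different rounds, so their responses were compared as the BMP gain response minus the BMP loss response. Vm32E again differed most, by -6.59 ± 0.12 (adjusted p = 3.9e-13), and Vm26Ac by -2.08 ± 0.13 (2.6e-06). bam differed by 2.12 ± 0.19 (0.00017), 18w by 1.72 ± 0.22 (0.0025), and the yolk genes Yp3 by 0.67 (0.0017) and Yp1 by 0.57 (0.0045). The fatty acid desaturase gene CG9747 and the transcription factor gene cbt differed the other way, by -1.76 ± 0.21 (0.0016) and -1.72 ± 0.26 (0.0073). The vitelline membrane list was lower, with 2 of 11 genes lower and 9 not called (4 lower adjusted over the list alone; 1.4e-06, and adjusted p = 0.0087 with an estimated correlation). The yolk list was higher, with 2 of 3 genes higher (3 adjusted over the list alone; 1.8e-08, and adjusted p = 0.0058 with an estimated correlation). No chorion or cell cycle gene was called, also adjusted over the lists alone. The chorion list was lower (0.0040; adjusted p = 0.71 with an estimated correlation) and the cell cycle list higher (0.0018; adjusted p = 0.51 with an estimated correlation). limma called 60 of 13966 probe sets, 30 higher and 30 lower, 43 by at least 2-fold, with 1113 at an unadjusted p under 0.05, and the calls of CG10512 and Swim ended with some arrays left out (highest adjusted p 0.089 and 0.12).

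Genes called in both EGFR perturbations against wild type A were compared in direction. A single probe set was called in opposite directions, that of 18w, which rose in EGFR gain (1.15) and fell in EGFR loss (-0.80). Of independent lists 6.18 opposite calls would be expected over both orientations together. Calls in both comparisons went the same way for 86 higher and 75 lower probe sets, against 3.58 and 2.67 expected of independent lists. Such calls, alike with the receptor active and blocked, may come from the strain or the driver. In 50 simulations of unchanged groups against the same controls 0 calls overlapped, here and over all 4 perturbations, which bounds nothing because groups without effects leave few calls to overlap. The correlation of the changes, across the brighter probe sets, which are not independent replicates, was 0.557 beside 0.502 from shared controls alone, and the covariance was 0.049 beside 0.015. The opposite call of 18w was lost, leaving 0, without wild type A replicate 1 or 3, and the count was 2 without EGFR gain replicate 1 or EGFR loss replicate 2 or 3.

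A set of 65 probe sets changed the same way in all 4 perturbations against wild type, 39 higher and 26 lower, against 0.00047 and 0.00038 expected of independent lists. Cyp28d1 rose by 5.56, 5.90, 4.504 and 3.29 in EGFR gain, EGFR loss, BMP gain and BMP loss, and Cyp6a17 by 4.66, 3.99, 4.21 and 4.84. The integrin gene mys rose by 0.81, 0.55, 0.71 and 0.86. PICK1 changed by -3.82, -3.17, -3.57 and -3.35, and numb, an inhibitor of Notch signalling, by -0.96, -0.71, -0.80 and -0.63. Of 101 probe sets called the same way in the 3 comparisons with wild type A, 98 had that sign in BMP loss against wild type B, which shares no array with them. Part of the excess within round 1 may come from the shared controls, which at 3 arrays could not be split. The count for genes changed the same way in all 4 perturbations, in probe sets, was 40 without wild type A replicate 2, 43 without wild type A replicate 3 and 4 in fits to the arrays of each comparison alone.

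**Figure D3:**
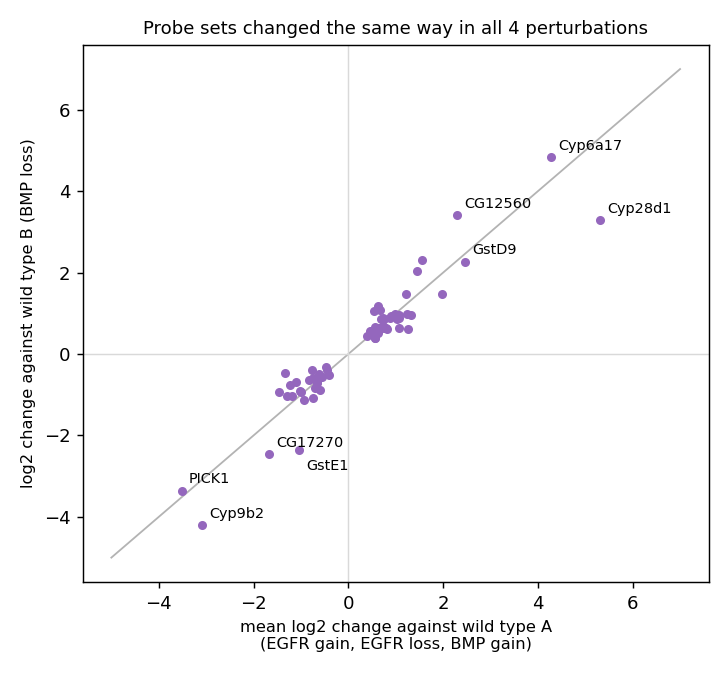
Mean log2 change over EGFR gain, EGFR loss and BMP gain against wild type A (horizontal) and log2 change of BMP loss against wild type B (vertical) of the 65 probe sets called the same way in all 4, with a grey line of equality. All points lie in the quadrants of equal sign, from Cyp28d1 and Cyp6a17 among the rises to PICK1 and Cyp9b2 among the falls.

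Wild type A and wild type B had the same genotype and differed in round. The median difference over probe sets was 0.44, and limma called 5350 of 13966, 5223 higher in wild type A and 127 lower. With each array centred on its median, which removes that shift, 2086 were called, 1064 higher and 1022 lower, and quantile normalization over the 18 arrays gave 2073, 1034 higher and 1039 lower. The difference between rounds exceeded that between any perturbation and its own control in number of calls. Ahcy, the gene with the lowest p, chosen after its values were seen, stood at 9.99 ± 0.03 in wild type A and 8.57 ± 0.03 in wild type B. GstD1, named above for its changes, stood at 10.09 ± 0.17 and 8.84 ± 0.09, a difference of 1.25 that is larger than the median shift. Levels were therefore not compared across rounds for the perturbations.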

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

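The test of neighbouring shared genes and all splits of the samples were planned before their results were seen, and every other test here was chosen after the pattern had been seen.

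Some genes had changes of opposite sign against wild type in EGFR gain and EGFR loss, with the difference itself called. kek1 differed by 3.70 (2.08 in EGFR gain and -1.62 in EGFR loss), CG46339 by 2.67 (2.07 and -0.60), Ugt36D1 by 2.38 (0.82 and -1.56) and 18w by 1.95 (1.15 and -0.80). Lower in EGFR gain were CG14636, at -2.46 (-1.37 and 1.09), CG33099, at -2.38 (-1.58 and 0.80), Cp15, at -2.30 (-1.53 and 0.77), Mlc1, at -2.88 (-0.85 and 2.02), Prm, at -1.82 (-0.50 and 1.31) and Timp, at -1.30 (-0.65 and 0.65). Between the BMP responses the same was seen for CG10512, at 4.62 (2.20 in BMP gain and -2.42 in BMP loss), dpy, at 2.62 (1.23 and -1.39), 18w, at 1.72 (1.14 and -0.58), Swim, at 1.49 (0.77 and -0.72), CG9747, at -1.765 (-1.09 and 0.68) and cbt, at -1.72 (-0.58 and 1.14). Not every change against wild type in these pairs was called, and where it was not its sign is a measured value without a call. In control probe sets that no comparison uses, the actin 3' minus 5' difference was 2.89 in EGFR loss replicate 3, 1.63 in EGFR gain replicate 3 and at most 1.20 in wild type A.

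The 65 probe sets that changed the same way in all 4 perturbations were weighed against noise of the shared wild type A arrays, linked stretches of chromosome and strain or driver. Of 101 probe sets called alike in round 1, 97.0% had the same sign in BMP loss against the other wild type, which argues against noise of the wild type A arrays. The chromosome arm with the most of the 55 shared genes held 25.5% of them, which argues against a single linked stretch as the cause of the whole set. For part of the set linked stretches stay open, since 7 of 55 had another within 10 genes, leaving out neighbours of the same Cyp or Gst family, between the median of 4 and the 95th percentile of 9 over 2000 random draws. Strain background or the GAL4 driver may account for the set and cannot be told apart from a response common to both pathways, since the design holds no group with the driver alone, and 6 of the 65 were called in EGFR gain against EGFR loss.

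Higher muscle and fat body genes in EGFR loss were weighed against degraded RNA in replicate 3 and carried-over tissue. In replicates 1, 2 and 3 the mean change from wild type A was 0.0028, 0.82 and 0.53 over muscle genes and 0.55, 1.05 and 1.59 over fat body genes, against highest wild type A arrays of 0.15 and 0.28. Without replicate 3 the muscle list still differed between EGFR gain and EGFR loss (adjusted p = 0.00083, but 0.10 with an estimated correlation). Its mean was -0.78 against -0.82 with that array, which argues against degraded RNA there as the whole cause of that difference. Part of the difference lay in EGFR gain, whose muscle mean against wild type A was -0.37, not called (0.22). For EGFR loss against wild type A the mean was 0.41 without replicate 3 and 0.45 with it. Camera called neither (0.071 and 0.079), so the difference does not establish a rise in EGFR loss itself. For fat body genes the call between EGFR gain and EGFR loss ended (0.22) in a test with fewer arrays, at a median of -0.50 against -0.54 and a mean of -0.72 against -0.98, which neither excludes degraded RNA nor speaks for it. Carried-over tissue, which hand dissection should limit, stays open too, since 5 of 16 muscle and 1 of 7 fat body genes already reached the table's median in wild type A, Act87E and Act79B (-0.18 and 0.14) among them, and an effect of EGFR loss was not tested.

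Lower eggshell genes in BMP gain were weighed against a younger mix of egg chambers, since stages 9 to 10 span the onset of these genes. Between arrays of a group the early chorion genes Cp7Fc, Cp36 and Cp38 moved together, with a mean correlation of 0.918, so a younger mix may account for their fall. For Vm32E its slope on the mean of all 7 chorion genes between arrays of a group was 0.089 ± 0.061. That slope predicts a change of -0.10, at the lowest -0.24, against the observed -6.45. Outside BMP gain Vm32E lay near the top of the scale and varied little, which can flatten the slope, so this prediction is a weak guide. In EGFR gain the chorion mean against wild type A was -0.76 with Vm32E at -0.84. In BMP gain they were -1.15 and -6.45. These group values argue against a younger mix alone, as read by the chorion genes, as the cause of the fall of Vm32E. A response to BMP signalling remains a hypothesis that was found and tested on the same arrays.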

How the results depend on the processing

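The actin covariate and the joint removal of both replicate 3 arrays of the EGFR groups were chosen after the data were seen. Of 223 summary counts under alternatives 140 lay within 1.5 times the reported count and 83 did not, and of 4254 values of single genes and lists 3618 kept direction and side of the threshold, 618 lost the call, 14 gained it and 4 changed sign with a move above the SE, all in genes that were not called; smaller changes of sign in uncalled genes were counted as kept. With single arrays left out br in EGFR gain ranged from -0.51 (without EGFR gain replicate 2) to 0.41 against wild type A and from -0.52 (the same array) to 0.39 against EGFR loss. Dad in EGFR loss ranged from -1.87 to 0.015 (without EGFR loss replicate 1), and aos in BMP loss from -0.996 (without BMP loss replicate 2) to 1.15; the cause was not tested. Counts are given in the order EGFR gain, EGFR loss, BMP gain, BMP loss, EGFR gain against EGFR loss, and EGFR gain against BMP gain.

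Fits to the arrays of a comparison alone called 62, 28, 95, 55, 2 and 41, with 0 opposite EGFR calls and 4 shared by all perturbations. They kept 67 of 204 named calls. Such fits have fewer residual degrees of freedom and do not borrow the spread of other groups. Over the brighter probe sets EGFR loss replicate 3 differed from replicates 1 and 2 by a median of 0.19 and 0.20. Arrays of any other group differed by at most 0.15. The shared spread may thus be too small for EGFR loss and its calls too many, which was not tested. Fits to a round alone called 215 and 227 in EGFR gain and loss, 55 in BMP loss, 157 and 78 in the direct comparisons, with 0 opposite, 12 shared and 124 of 188 named calls; they give no value across rounds. Moderation with a trend raised EGFR loss to 725, BMP loss to 488, the direct comparisons to 446 and 281, and opposite calls to 6, and array weights raised BMP gain to 578; the cause was not tested. With dim probe sets left out, so that fewer were tested, EGFR gain gave 614, EGFR loss 752, BMP loss 534, the direct comparisons 497 and 288, opposite calls 7, shared calls 103 and lists 8. A 2-fold minimum left 99, 120, 104, 83, 88 and 66, 1053 between wild types, 0 opposite and 12 shared. Between wild types quantile normalization gave 2073 and median centring 2086, by removing the shift between rounds. The actin covariate gave 3 opposite calls, and both replicate 3 arrays left out gave 175 for EGFR gain against EGFR loss and 2 opposite calls; the cause was not tested. Over the comparisons with wild type and EGFR gain against EGFR loss, 6 of 16 list calls held with an estimated correlation, and fry, which tests another hypothesis, called 35, of which 15 were shared. All 6 wild types with the round as a block gave the same fit by construction. An offset for linear values was not run because the table is already on a log scale.

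Single arrays left out, with fewer samples, gave 219 to 318 in EGFR gain, 233 to 438 in EGFR loss, 210 to 256 in BMP gain, 183 to 263 in BMP loss, 173 to 270 in EGFR gain against EGFR loss and 89 to 138 in EGFR gain against BMP gain. They gave 45 to 58 for the BMP difference, 4666 to 4852 between wild types and 0 to 2 opposite calls. For genes changed the same way in all 4 perturbations they gave 40 to 62 probe sets. The number of named calls kept depends on how many an array bears on. It ran from 33 of 42 (without wild type B replicate 3) to 93 of 123 (without wild type A replicate 1). Only without EGFR gain replicate 1 did the named calls, 58 of 88, fall beyond 1.5 times.

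The replicate number does not pair the arrays, since 21 same-numbered pairs had correlations of deviations from -0.15 to 0.34 with a median of 0.026, and 4 lay over 0.1. With the number as a block, 241, 251, 186, 167 and 102 probe sets were called in EGFR gain, EGFR loss, BMP loss and both direct comparisons, with 35 for the BMP difference and 35 shared calls. Signal over background limits the dim genes. The brighter group lay under the median of all means for 29 of 392 calls in EGFR gain, 46 of 443 in EGFR loss, 30 of 334 in BMP gain and 42 of 320 in BMP loss, and folds there depend on the background correction.

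Other splits of the 6 arrays gave at most 2 calls in EGFR gain (392 in the real split), 1 in EGFR loss (443), 1 in BMP gain (334), 3 in BMP loss (320), 2 in EGFR gain against EGFR loss (293), 2 in EGFR gain against BMP gain (178) and 3 between wild types (5350). With 10 splits, of which 1 was as large in each case, they are too few for a share under 0.05. Of 100 splits only the real one gave as many calls in the BMP difference (60, highest other 35). The same held for probe sets changed the same way in all 4 perturbations (65, highest other 1). Other splits mix groups that differ, which widens the spread and lowers their counts beforehand. Samples of a genotype came from the same 300 egg chambers, so splits cannot exclude a chance difference between collections. For opposite calls 1 of 100 splits gave as many (1, highest other 0), which rests on 18w alone and is lost without wild type A replicate 1 or 3. For list calls 2 of 100 gave as many, since another split equalled the real one (16 and 16).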

Other observations

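The tests behind these values follow lists and comparisons planned before the data were examined, and the grouping of glutathione S-transferase genes by family was chosen after their values were seen.

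Several glutathione S-transferase genes changed in all 4 perturbations, the GstD members among them upward and the GstE members downward except GstE11. GstD1 rose by 1.57, 1.58, 1.53 and 2.30 in EGFR gain, EGFR loss, BMP gain and BMP loss (highest adjusted p = 6.3e-07), and GstD9 by 3.02, 2.13, 2.24 and 2.27 (0.0070). In the same order GstE1 changed by -0.86, -1.16, -1.11 and -2.35 (0.0023), GstE8 by -0.81, -0.61, -0.82 and -1.09 (0.040), and the microsomal transferase gene Mgstl by -0.94, -1.15, -0.95 and -0.90 in the brightest of its 3 called probe sets (0.00026). GstE11 rose by 0.44, 0.88, 0.53 and 1.17 (0.0068). GstE7 was called in BMP loss alone, at -3.44 ± 0.25 (6.3e-06), against -0.65 (0.31) in BMP gain, and the difference between the BMP responses was called at 2.79 ± 0.36 (0.0025). Within the cytochrome P450 family Cyp12d1-d rose in all 4, by 2.20, 1.00, 0.79 and 0.96 (0.041), and Cyp6a9 changed by -1.50, -1.22, -1.13 and -1.02 (0.026). Cyp12d1-d was higher in EGFR gain than in EGFR loss by 1.20 ± 0.19 (0.0038).

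Of the 24 gene lists 15 were called by camera in none of 7 comparisons. Their lowest adjusted p-values were 0.18 for EGFR pathway components, 0.57 for dorsal appendage and follicle patterning, 0.38 for dorsoventral axis components, 0.079 for germline genes, 0.62 for border and polar cells, 0.60 for hemocytes and 0.51 for neurons. Signalling and stress lists stood at 0.13 for JAK/STAT, 0.11 for Notch, 0.40 for Hedgehog and Wnt, 0.62 for ecdysone, 0.50 for heat shock, 0.071 for JNK and apoptosis, 0.28 for epithelial junctions and polarity and 0.59 for detoxification. These values are from camera, and fry called some of the same lists. By fry, detoxification was called in EGFR gain (adjusted p = 0.0070), EGFR loss (0.0024) and BMP gain (0.0018). JNK and apoptosis was called by fry in EGFR loss (0.00018), BMP loss (0.0079) and EGFR gain against EGFR loss (0.0023). EGFR pathway components were called by fry in BMP loss (0.0063), EGFR loss (0.019) and EGFR gain against EGFR loss (0.023). In that direct comparison fry also called dorsal appendage and follicle patterning (0.023) and JAK/STAT (0.037), and in EGFR loss germline (0.037). Fixed patterning genes without a call against wild type in any perturbation were pip, br, dpp, Cad74A, aos and sty. The pipe gene pip, which is repressed by EGFR in dorsal follicle cells, stood at -0.71 ± 0.71 in EGFR gain (0.76) and 0.92 ± 0.71 in EGFR loss (0.57), signs that were not called.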
